A study of Mus musculus with 62 samples.

How the data were processed

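The series holds 62 samples of chromatin immunoprecipitation and sequencing from mouse B cells, 19 for H3K4me1, 18 for H3K4me3 and 25 inputs, from 8 populations. Per the labels' protocols, cells were sorted on instruments of 3 kinds, fixed with 1% formaldehyde and sonicated to fragments of about 500 bp, and the DNA was recovered with phenol and chloroform and made into Illumina libraries. The labels do not say which sorter, day or batch a sample came from, so no comparison within a batch was made. Per the submitters' processing notes, the tools were CASAVA 1.8.1, BWA 0.7.8 and MACS2 2.0.10 with the mm10 genome. The notes give no roles, settings or thresholds for these tools.

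The deposited values used were 16 peak lists, 1 per population and mark. The file labels describe joined replicates, so a list is 1 pooled measurement with no error of its own, and single replicates could not be set against each other or left out. Each list gives a peak's position, a fold over input as the authors' caller wrote it, and the -log10 of a p-value and of a q-value, also deposited by the authors. The fold is a ratio. It and the -log10 values belong to a single peak in a single list, and they were used to describe, rank or filter peaks within that list. For a gene or region marked in several lists, the highest -log10 p also decided which list's peak is shown, and this makes no claim about levels between lists. Peak names carry running numbers far above the length of the list, up to 385103 in the Marginal H3K4me3 list of 19025 peaks, so each list is a part of a longer one. How that part was chosen is not given in the sources used here. Lists hold no read totals, so depth per sample is unknown and no interval for counting error was computed. Samples of 1 group are separate by label, and whether they came from separate mice is not given in the sources used here. The inputs entered only through the authors' fold.

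Positions were counted from 1 and taken as mm10. Genes came from a RefSeq table for GRCm38.p6, the assembly of mm10, with 49943 genes on the assembled chromosomes, of which 21887 are protein-coding and 12727 lncRNA. The table gives each gene's span without strand or transcription start sites. A gene was therefore called marked when a peak lay within 1 kb of either end of its span, in place of the start sites planned. A promoter inside the span is missed by this rule and a peak at the far end of a gene is counted. Far lncRNA genes had no protein-coding gene end within 10 kb, and near ones had 1 within 2 kb. Overlap meant at least 1 bp. Distal H3K4me1 peaks lay more than 1 kb from every annotated gene end and were given to genes within 10 kb. V segments counted as marked with a peak within 500 bp. Breadth was the number of base pairs under H3K4me3 peaks within 5 kb of a gene end, and the top 5% of marked protein-coding genes were taken as broad. Equal-length lists held the strongest 4380 H3K4me1 or 14715 H3K4me3 peaks by the authors' -log10 p, the length of the shortest list of each mark.

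The grouping, the tests, 21 gene lists, the rule for naming genes and the other settings to try were fixed before the data were examined. The 8 populations were the units of exact permutation tests, between bone marrow and the other tissues (4 against 4) or by sign flips over 8 paired differences. The 7 pairs of neighbouring populations gave 14 directions, in which a gene was called when an H3K4me3 peak of the equal-length list lay at an end and the full list of the other population had none there. Gene lists were tested with Fisher's exact test against the protein-coding genes marked in either population, with Benjamini-Hochberg adjustment over 314 tests and a threshold of 0.05. These tests describe the lists, since genes are not independent replicates. Genes named in a direction were members of the fixed lists and, outside them, up to 6 protein-coding genes and 4 lncRNA genes with the highest -log10 p. Genes that the sort itself selects on (Cd5, Fcer2a, Fas, Cd38, Cd2, Cd19, Cd93 and Ptprc, for Cd5, Cd23, Fas, Cd38, Cd2, Cd19, AA4.1 and B220) are no independent finding in the populations gated on them.

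The other settings fixed then were windows of 500 bp and 2 kb, a -log10 q of at least 5, full or equal-length lists, merging within 500 bp, 50 kb for distal peaks, at least 50% overlap, the top 10% by breadth, Pro, Pre and Immature against the other 5 populations, and leaving out each population. Alternatives chosen after seeing the data were absence from the whole gene, peaks at no other gene end, peaks that overlap none of the other list, peaks anywhere in the gene, leaving out populations for the lncRNA shares, limiting the specificity test to lists with genes marked there alone, and as background near lncRNA genes, gene positions moved by 1 Mb (for far lncRNA genes, those still far from protein-coding gene ends), olfactory receptor genes and T-cell receptor V segments. A further list of 20 granulocyte genes and another of 20 macrophage genes were written after the main values were seen and before their own peaks were looked at.

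The code of the calls was tested on simulated data. Peaks were deleted outright, so the counts show that the code follows the rule and measure no error on real lists, for which replicate values would be needed. In each of the 7 pairs, a copy of the first-named population's H3K4me3 list lost the peaks at 200 genes and then the weakest 10% of its peaks. Marginal, Germinal and B1a were never first-named. All 200 genes were recovered in each simulated pair over 34614 genes. Calls at genes with no removed peak numbered 0 in 6 pairs and 445 for Pre over Immature, where the equal-length list of Pre is its full list, while full lists gave 261 to 445 such calls. Removing the distal H3K4me1 of 200 genes from the Follicular list recovered 200. Of 1000 random lists of 20 genes tested for Germinal over Follicular (10903 genes), 0.3% had p under 0.05. Interval overlaps were checked against bedtools 2.31.1 and the permutation tests against scipy 1.17.1. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.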

Results

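Histone marks were mapped by chromatin immunoprecipitation and sequencing in 8 B-cell populations sorted from female C57BL/6JNimr mice aged 7 to 9 weeks. Pro, Pre, Immature and Mature cells came from the bone marrow, Follicular, Marginal and Germinal cells from the spleen, and B1a cells from the peritoneal cavity. The spleens that gave the Germinal cells came from mice immunised with sheep red blood cells. The marks were H3K4me3, which sits mainly at promoters, and H3K4me1, which is found at enhancers and around promoters. The series concerns long non-coding RNAs in B cells, so the question put to the lists was which genes, coding and non-coding, carried each mark in which population. The 62 samples comprised 19 for H3K4me1, 18 for H3K4me3 and 25 inputs, with 2 to 3 immunoprecipitated samples per population and mark and 3 to 4 inputs per population. The values analysed were 16 peak lists, 1 for each population and mark, made from joined replicates. No value of a single replicate was analysed, so the population was the unit in tests between populations, while tests of gene lists and of peak breadth counted genes. The sequencing depth behind a list is unknown, because a list holds peaks and no read totals.

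The H3K4me1 lists differed far more in length than the H3K4me3 lists. Follicular and Marginal had the most H3K4me1 peaks, 44479 and 42399, followed by Mature with 33897. B1a had 20497, Germinal 16415, Pre 10264, Immature 5318 and Pro 4380. The longest H3K4me1 list was 10.2 times the shortest. For H3K4me3 the ratio was 2.12, from 31242 peaks in B1a and 25280 in Mature down to 16750 in Germinal and 14715 in Pre. Pro held 20508 H3K4me3 peaks, Immature 19298, Marginal 19025 and Follicular 18691. The bone marrow lists averaged 13465 ± 13864 H3K4me1 peaks (SD, n = 4) and the lists of the other tissues 30948 ± 14545 (SD, n = 4), a difference of -17483 that did not pass a two-sided exact permutation test (p = 0.171, where the smallest p of the 70 splits was 0.0286). With Pro, Pre and Immature set against the other 5 populations, a grouping that also follows the stage of the cells, the difference in H3K4me1 number was -24883 (exact permutation p = 0.0357). For H3K4me3 the averages were 19950 ± 4342 and 21427 ± 6620 (SD, n = 4 each), a difference of -1477 (two-sided exact permutation p = 0.743). Across the 8 populations the numbers of H3K4me1 and H3K4me3 peaks gave Pearson r = 0.132 (exact permutation p = 0.775) and Spearman rho = -0.0238 (exact permutation p = 0.977). This was the only correlation computed, and without Follicular and Marginal, the populations farthest from the median H3K4me1 number, r was 0.542 (exact permutation p = 0.281, n = 6).

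**Figure D1:**
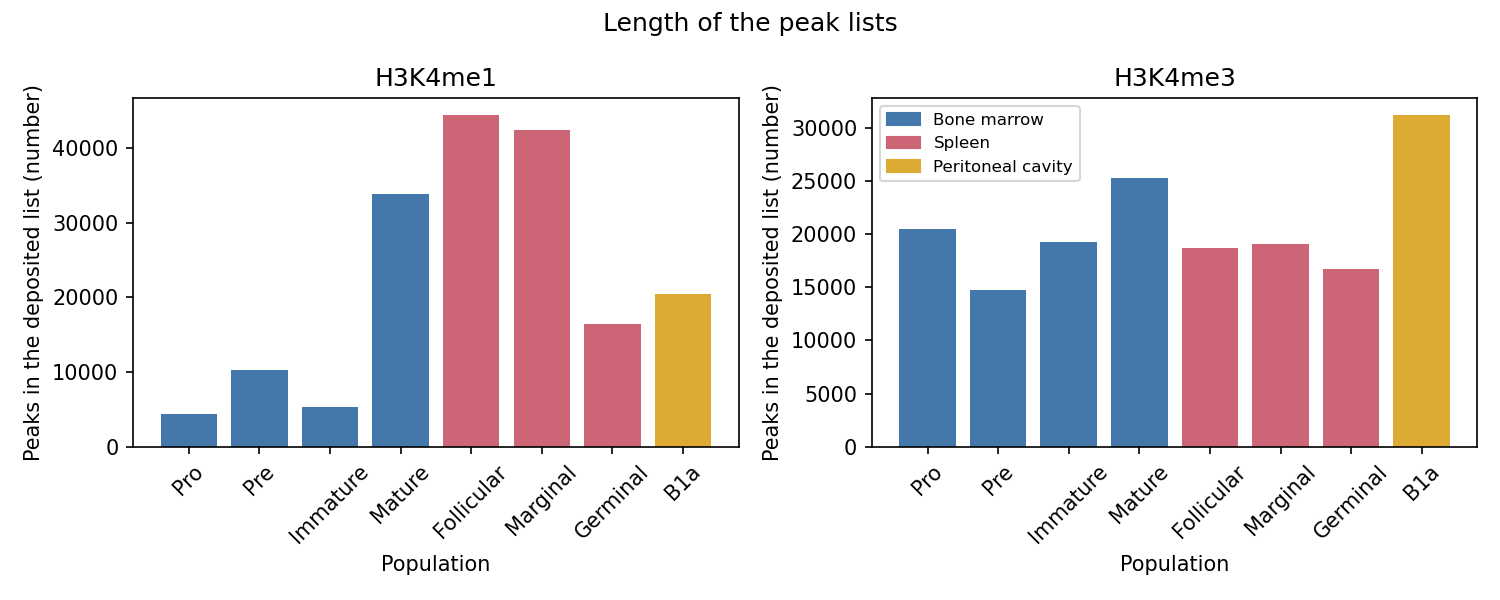
Number of peaks (vertical axes) in the deposited list of each population (horizontal axes), H3K4me1 on the left and H3K4me3 on the right, with bars coloured by tissue and no error bars because each list joins its replicates. H3K4me1 runs from 4380 peaks in Pro to 44479 in Follicular, and H3K4me3 from 14715 in Pre to 31242 in B1a.

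The Pro H3K4me1 list stood apart in strength as well as in length. Its peaks had a median width of 220 bp, and 14 of them, 0.32%, reached a -log10 q of 5. In the other 7 H3K4me1 lists every peak reached that level, and median widths ran from 695 bp in Immature to 1487 bp in Marginal. Every H3K4me3 list except Germinal, with 91.0%, also held only such peaks. Of the H3K4me3 peaks, 84.4% in Pre, 79.6% in Marginal, 78.1% in Follicular and 78.1% in Germinal lay within 1 kb of an annotated gene end, against 60.1% in Mature and 54.8% in B1a, the longest lists.

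To compare where the marks lay, each list was limited to its strongest peaks, 4380 for H3K4me1 and 14715 for H3K4me3, and scored by the base-pair Jaccard index, the shared length divided by the total length covered. H3K4me1 was most alike among Mature, Follicular and Marginal, with indices of 0.361 for Mature and Follicular, 0.367 for Mature and Marginal and 0.378 for Follicular and Marginal. Pre was more like Marginal (0.168), Follicular (0.163) and Mature (0.155) than like Immature (0.132), and Pro shared between 0.0221 and 0.0473 with the other populations. The index is limited where lists cover unlike lengths. Pro peaks, with a median width of 220 bp, covered 1.10 Mb, so the low Pro values do not show that its marks lie elsewhere. H3K4me3 was shared far more widely, led by Mature with B1a at 0.762 and Pro with Immature at 0.758, and it was lowest for Marginal with B1a at 0.41. The same limit holds here, as median H3K4me3 widths in the full lists were 553 bp in Marginal, 992 in B1a and 1030 in Mature. The low value for Marginal with B1a therefore does not show that the mark lies elsewhere. Pairs of populations from the same side, bone marrow or other tissue, averaged 0.131 for H3K4me1 (12 pairs) and pairs across 0.122 (16 pairs), a difference of 0.00816 (one-sided exact permutation p = 0.171 over 35 splits, the smallest possible being 0.0286). For H3K4me3 the averages were 0.616 and 0.606, a difference of 0.00998 (one-sided exact permutation p = 0.314). Grouping Pro, Pre and Immature against the other 5 populations gave a difference of 0.0947 for H3K4me1 (exact permutation p = 0.0357), and leaving out Mature, the bone marrow population most like the spleen, gave 0.0641 (exact permutation p = 0.0286). The 0.0947 came from likeness among the other 5 populations, whose 10 pairs averaged 0.207, because the 3 pairs of Pro, Pre and Immature averaged 0.0744, no more than the 15 pairs across at 0.0819. Leaving out Follicular, Marginal, Germinal or B1a turned the difference to -0.0104, -0.00813, -0.00257 or -0.01. The H3K4me3 difference turned to -0.0234 with the Pro, Pre and Immature grouping.

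**Figure D2:**
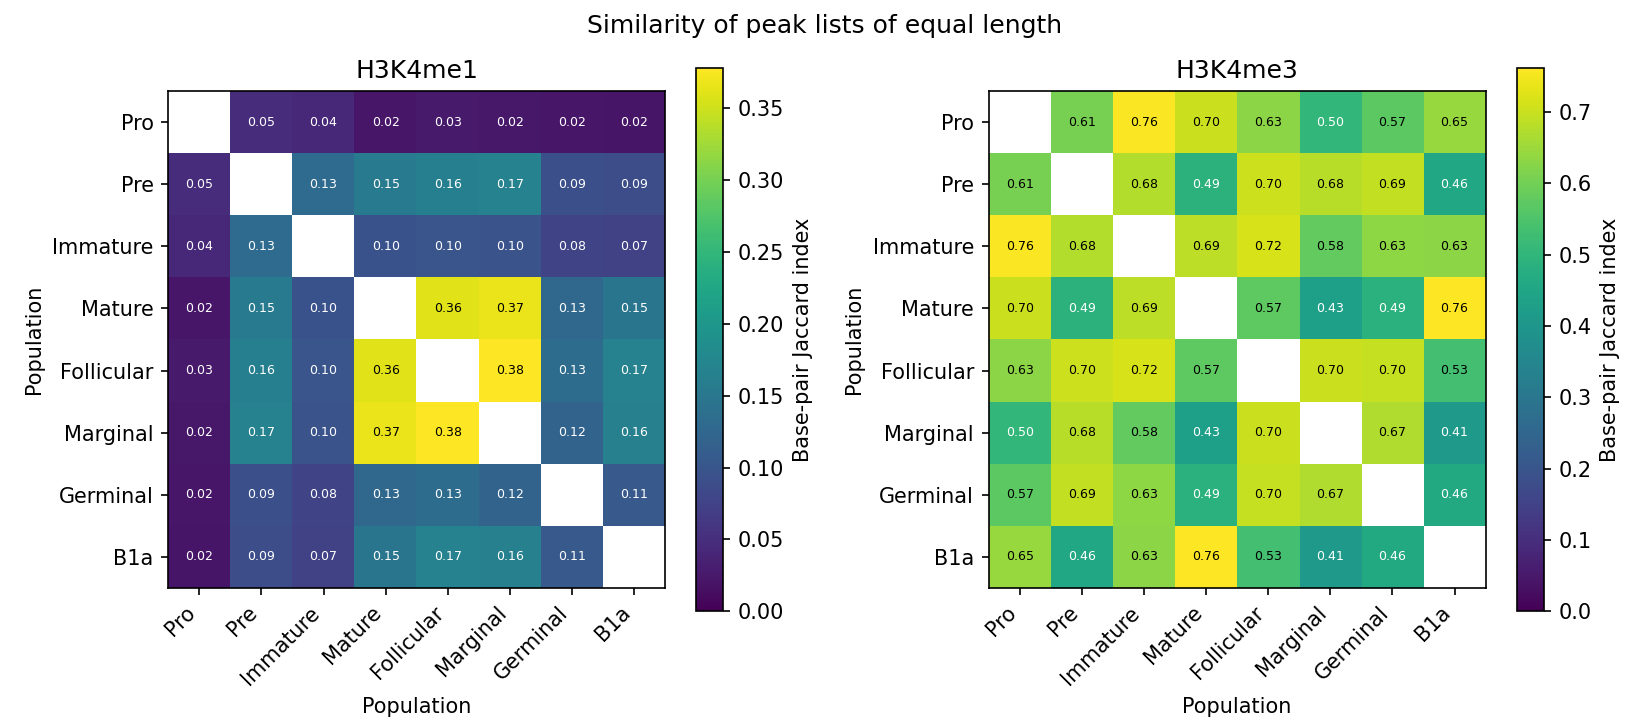
Base-pair Jaccard index (colour scale and printed values) for every pair of populations, which form both axes, in lists limited to the strongest 4380 H3K4me1 peaks (left) and 14715 H3K4me3 peaks (right). Mature, Follicular and Marginal form the brightest H3K4me1 block at 0.361 to 0.378, and Pro is the darkest line at 0.0221 to 0.0473.

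When overlapping peaks of all populations were merged, 32254 H3K4me3 regions resulted, of which 10521 (32.6%) had a peak in all 8 populations and 10550 (32.7%) in a single population. The H3K4me1 lists merged into 49958 regions, of which 640 (1.28%) were found in all 8 populations and 28.9% in a single population. A region in all 8 needs a peak in Pro, whose H3K4me1 list held only 4380, so list length limits the shared part. B1a accounted for 7545 of the H3K4me3 regions seen in a single population, Mature for 1451, Germinal for 769, Pro for 587, Marginal for 151, Immature for 41, Follicular for 5 and Pre for 1. Among H3K4me1 regions seen in a single population, Marginal held 4831, Follicular 3763, Mature 1918, Germinal 1575, B1a 1477, Pre 450, Pro 293 and Immature 118. On lists of equal length 61.7% of H3K4me3 regions were found in all 8 populations and 12.0% in a single population. For H3K4me1 the equal-length shares were 0.972% in all 8 populations and 56.7% in a single population. Those lists held 4380 peaks for H3K4me1 and 14715 for H3K4me3, so the shares of the marks are not on equal terms.

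H3K4me3 was found at far fewer long non-coding RNA (lncRNA) genes than protein-coding genes in every population. A gene was called marked when a peak lay within 1 kb of either annotated end, because the annotation used gives no strand. Of 12727 lncRNA genes, 16.0% ± 3.67 (SD, n = 8 populations) were marked, against 50% ± 4.24 of 21887 protein-coding genes (SD, n = 8). The difference was -34.0 percentage points ± 0.834 (SD), with the lncRNA share lower in 8 of 8 lists (two-sided exact sign-flip permutation p = 0.00781, the smallest that 8 lists can give). Among lncRNA genes the share differed by position, though a peak at a gene near a protein-coding gene can belong to that neighbour. Which of them it belongs to was not tested. Of the 2720 with a protein-coding gene end within 2 kb, 50.1% ± 5.72 were marked (SD, n = 8), and of the 7643 with none within 10 kb, 5.03% ± 2.7 (SD, n = 8), a difference of 45.1 points ± 3.12 (SD, exact sign-flip permutation p = 0.00781, higher in 8 of 8 lists). The share of these far lncRNA genes ran from 2.53% in Pre to 10.3% in B1a. As a background chosen after the data were seen, their positions were moved by 1 Mb and the 5348 that again had no protein-coding gene end within 10 kb were kept. These gave 1.15% ± 0.77 (SD, n = 8), 3.88 points ± 1.94 (SD) under the observed share, which was higher in 8 of 8 lists (two-sided exact sign-flip permutation p = 0.00781). Protein-coding genes moved by 1 Mb gave 4.21% to 9.48%, and olfactory receptor genes, a large family silent in B cells, gave at most 0.271%.

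**Figure D3:**
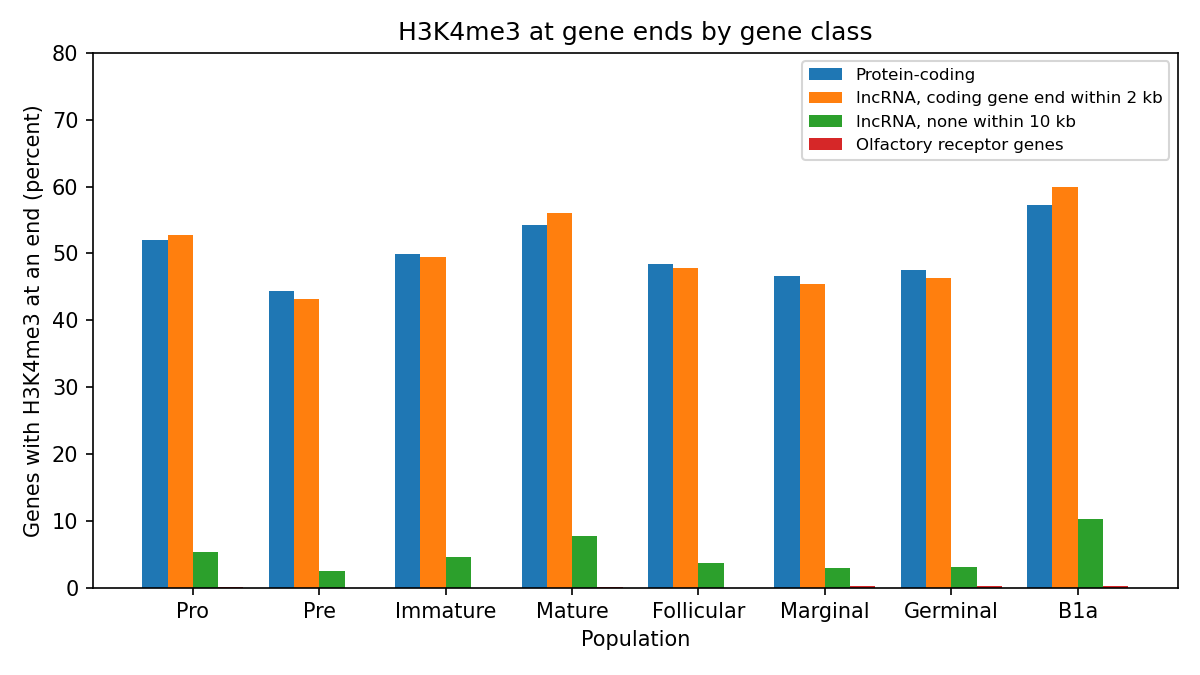
Percent of genes with an H3K4me3 peak within 1 kb of an end (vertical axis) in each population (horizontal axis), as bars for protein-coding genes, lncRNA genes with a coding gene end within 2 kb, lncRNA genes with none within 10 kb, and olfactory receptor genes. Far lncRNA genes range from 2.53% in Pre to 10.3% in B1a, and olfactory receptor genes stay at or under 0.271%.

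Genes marked in any population numbered 12799 of the protein-coding class (58.5%), 3070 of the lncRNA class (24.1%) and 871 of the far lncRNA class (11.4%). Of the marked protein-coding genes, 73.5% (9401) carried H3K4me3 in all 8 lists and 6.46% (827) in a single list. Of the marked far lncRNA genes, 16.9% (147) carried it in all 8 lists and 33.6% (293) in a single list, 227 of these in B1a, the list with the most marked far lncRNA genes. Against protein-coding genes of the same peak rank the share marked in a single list was 1.72 points higher on average over 8 lists (exact sign-flip permutation p = 0.0625). Among the 27 lncRNAs listed by name, Malat1, Neat1, Pvt1 and Xist were marked in all 8 lists, and Meg3, H19 and Hotair in none. Hotairm1, at the Hoxa cluster on chromosome 6 (52158524 to 52162020, mm10), was marked in 7 lists and not in Pre. Mir155hg, the host gene of the microRNA miR-155, was marked in Pro, Mature and B1a, and Miat in B1a alone.

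H3K4me1 without H3K4me3 was more frequent at far lncRNA genes than at protein-coding genes, and its difference from moved positions depended on which of these were kept. Among genes with either mark at an end, with H3K4me1 taken from the equal-length lists, H3K4me1 alone was found at 23.8% ± 13.4 of far lncRNA genes and 0.686% ± 0.412 of protein-coding genes (SD, n = 8 each). The difference was 23.2 points ± 13.0 (SD), higher in 8 of 8 populations (two-sided exact sign-flip permutation p = 0.00781). The far lncRNA share was highest in Marginal at 41.3%, Pre at 38.7% and Follicular at 33.7%, and lowest in B1a at 5.08%. It was 27.5% in Germinal, 18.1% in Immature, 14.7% in Pro and 11.7% in Mature. H3K4me3 entered as full lists, and the lowest shares belonged to the longest of these. They were B1a with 31242 peaks, Mature with 25280, Pro with 20508 and Immature with 19298, so this order can reflect list length. Of the marked positions among those moved by 1 Mb and still far from protein-coding gene ends, 45.7% ± 17.4 (SD, n = 8) had H3K4me1 alone. The observed far lncRNA share differed from this by -21.8 points ± 5.45 (SD) and was lower in 8 of 8 populations (two-sided exact sign-flip permutation p = 0.00781). With all moved positions, which include some at protein-coding gene ends, the background was 18.4% ± 8.17 (SD, n = 8) and the observed share was 5.4 points ± 6.03 (SD) higher, in 6 of 8 populations (two-sided exact sign-flip permutation p = 0.0391). Both backgrounds were chosen after the data were seen. Near lncRNA genes had H3K4me1 alone at 1.18% ± 0.918 (SD, n = 8), 0.497 points above protein-coding genes (exact sign-flip permutation p = 0.0234). The difference between far lncRNA and protein-coding genes was 40.2 points with full H3K4me1 lists and 38.7 with a -log10 q of at least 5.

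The gene lists chosen in advance showed which programmes carried H3K4me3 at a gene end. Of the 22 core B-lineage genes, such as Cd19, Cd79a, Pax5 and Ebf1, all were marked in 6 populations and 20 in Pro and in Pre, which lacked Ms4a1, encoding CD20, and Bank1, an adaptor of B-cell receptor signalling. Of 22 pro-B and pre-B genes, 21 were marked in Pro, 16 in Immature, 13 each in Pre, Mature and B1a, 10 each in Follicular and Marginal, and 8 in Germinal. Of 18 mature and follicular B genes, 11 were marked in Pro, 9 in Pre, 13 in Immature, 16 each in Mature, Follicular and Marginal, and 15 each in Germinal and B1a. All 17 germinal centre genes were marked in Germinal, against 15 in B1a, 14 in Mature, 13 each in Pro, Immature, Follicular and Marginal, and 9 in Pre. All 13 B1 genes were marked in B1a, against 9 in Mature, 8 each in Pro, Immature, Follicular and Marginal, and 6 each in Pre and Germinal. Of 13 marginal zone genes, 10 were marked in Marginal, in Mature and in B1a, 9 each in Pro, Immature, Follicular and Germinal, and 7 in Pre.

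Genes of common cell functions varied little. Of 21 cell cycle genes, 20 were marked in Pre, which lacked Ccna2, and 21 in each of the other lists. Of 14 housekeeping genes, 12 were marked in Pre, which lacked the glycolysis gene Pgk1, and 13 elsewhere. Ywhaz was marked in no list. The window misses promoters that lie inside the annotated span of a gene, and whether this holds for Ywhaz was not tested. Of 17 immediate early and NF-kB genes, 15 to 17 were marked, of 16 antibody diversification and repair genes 13 or 14, and of 12 plasma cell genes 8, or 9 in Germinal. Homing receptors numbered 14 of 16 in Mature and B1a and 7 in Pre, Toll-like receptors 12 of 15 in Mature and B1a and 5 in Pre, and the named lncRNAs 22 of 27 in B1a and 17 in Pre. Markers of other cells were mostly unmarked. T-cell markers numbered 7 of 17 in B1a and 1 to 4 in the other lists, myeloid markers 8 of 17 in Mature, 5 in B1a, 4 in Pro, 3 in Immature and at most 2 elsewhere, and natural killer markers at most 2 of 9. Erythroid markers numbered 4 of 10 in Mature and B1a and 1 or 2 elsewhere, dendritic cell markers 1 to 4 of 8, and stromal markers at most 3 of 9. Of 20 regulators of development outside blood, 10 were marked in B1a, 6 in Mature and at most 2 elsewhere.

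**Figure D4:**
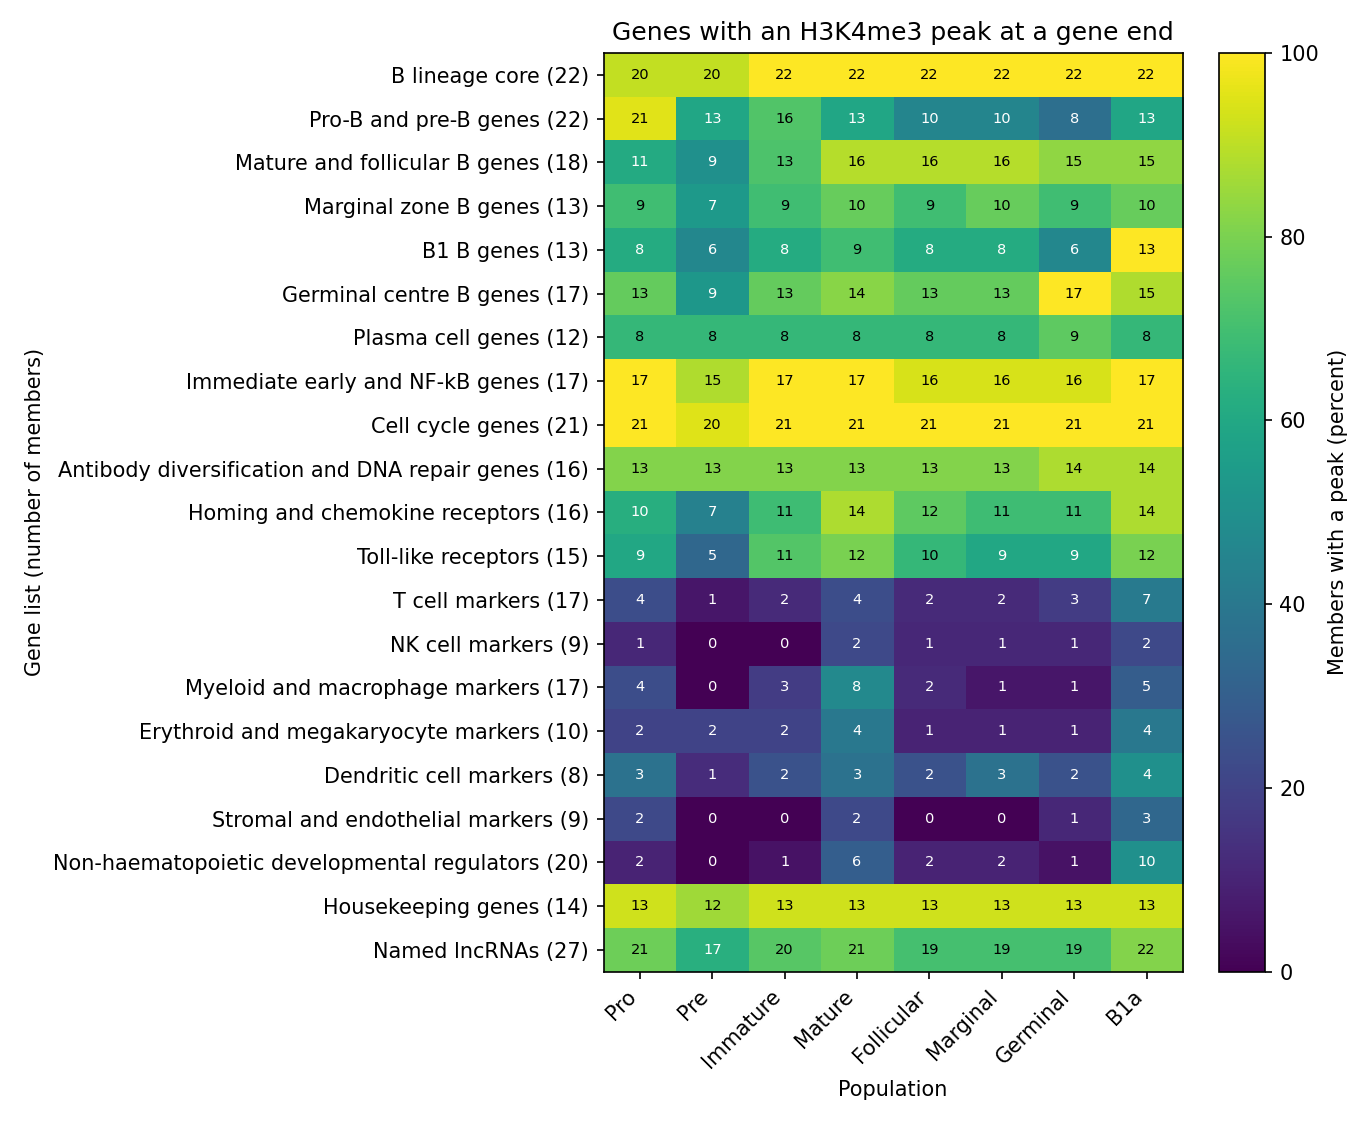
Members of each gene list (vertical axis, with list size) that had an H3K4me3 peak at a gene end in each population (horizontal axis), as printed counts over a colour scale in percent of the list. Germinal centre genes reach 17 of 17 in Germinal, B1 genes 13 of 13 in B1a, and pro-B and pre-B genes 21 of 22 in Pro.

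For each pair of neighbouring populations, a gene was called for X over Y when X had an H3K4me3 peak among its strongest 14715 at a gene end and the full list of Y had none there. Joined lists leave no replicates for a test of single genes, so these calls carry no p-value. Not all called lncRNA genes were far ones, so a called peak can belong to a protein-coding neighbour. Far lncRNA genes were 84 of the 264 called for Pro over Pre and 51 of 188 for Immature over Pre. They were 43 of 120 for Mature over Follicular and 66 of 198 for B1a over Follicular. A called gene can still have a peak that overlaps one of Y lying more than 1 kb inside the gene or at a neighbour, and the number whose strongest peak overlapped none in Y is given beside each count. The genes named below are those whose peak overlapped none, unless stated, a choice made after the values were seen. A gene called in this way can have a separate peak in Y farther inside it, which is stated where it holds for a named gene. The fold of a peak over input, as the authors give it, describes that peak within its own list.

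Pro cells, the earliest stage sampled, had H3K4me3 at the surrogate light chain gene Igll1 (fold 28.7, gene on chromosome 16, 16860671 to 16863985), at Dntt (16.2), which adds nucleotides to V(D)J junctions, at the receptor gene Kit (21.3), at Arpp21 (25.1) and at Enpep (17.1), all without a peak in Pre at or inside the gene. The gate that parted them was Cd2. In all, 1051 genes were called for Pro over Pre, 787 protein-coding and 264 lncRNA, of which 879 had a peak overlapping none in Pre. Of the 21 pro-B and pre-B genes in the background, 6 were called, the sixth being Vpreb1, whose peak overlapped one in Pre. This was 28.6% of the list against 6.91% of the background and did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0728 over 314 tests). The lncRNAs Hotairm1 (fold 22.3), Fendrr (12.9) and Ftx (11.1, with a Pre peak farther inside), the T-cell factor gene Tcf7 (20.9), the myeloid factor gene Cebpa (14.7) and the housekeeping gene Pgk1 (23.6) were called too. T-cell markers numbered 2 of 5 called and myeloid markers 2 of 4, and neither list passed. With full lists both passed (4 of 5, Fisher's exact adjusted p = 0.0396, and 4 of 4, Fisher's exact adjusted p = 0.0198). The 6 protein-coding genes with the strongest called peaks, Mmp11, Rab40b, Prkar1a, Ss18, Lcat and Inpp5k, all had a peak that overlapped one in Pre. The opposite direction held 8 genes, 5 of them with a peak overlapping none in Pro, among the 8 Il2ra (fold 6.36) and the class II invariant chain gene Cd74 (5.54). Of the 1051 genes, 336 (32.0%) were marked in every list except Pre, the shortest list, and full lists gave 2284 genes.

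Immature cells, which carry surface IgM, had H3K4me3 at several listed B-cell genes whose ends were unmarked in the Pre list. They included Ms4a1 on chromosome 19 (fold 29.5, peak 11263266 to 11266256), Bank1 (23.0), the Toll-like receptor genes Tlr9 (27.9), Tlr1 (25.9) and Tlr4 (10.5), the costimulatory gene Cd86 (28.7), the cytokine receptor gene Il21r (26.3), Fcrl1 (26.2, with a Pre peak farther inside), the follicle-homing receptor gene Cxcr5 (18.4) and the class II gene H2-Aa (11.2). In all, 754 genes were called, 566 protein-coding and 188 lncRNA, and 621 had a peak overlapping none in Pre. Among the lists, 4 of 11 Toll-like receptor genes (Fisher's exact adjusted p = 0.0689) and 4 of 13 germinal centre genes (Fisher's exact adjusted p = 0.0916) were called, and neither passed. With full lists, 6 of 11 Toll-like receptor genes were called and the list passed (Fisher's exact adjusted p = 0.0198). Mature and follicular genes numbered 3 of 13 (Fisher's exact adjusted p = 0.421). T-cell markers numbered 2 of 3, Tcf7 (fold 18.98) and Cd3d (12.2) (Fisher's exact adjusted p = 0.187), and myeloid markers 1 of 3, Cd68, whose peak overlapped one in Pre, though with full lists 3 of 3 myeloid markers were called and passed (Fisher's exact adjusted p = 0.035). The opposite direction held 8 genes, including Il2ra, and 6 of the 8 had a peak overlapping none in Immature. Of the 754 genes, 358 (47.5%) were marked in every list except Pre, and full lists gave 1648.

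Mature bone marrow cells had H3K4me3 at Cr2 (fold 51.6, gene on chromosome 1, 195136811 to 195176880), the complement receptor CD21, at Gpr183 (49.7), which guides B cells within follicles, at the homing integrin gene Itgb7 (35.3), at Tnfrsf13b (26.4), the receptor TACI, and at Ccr6 (19.4), none of them marked at a gene end in Immature. Itgb7 and Tnfrsf13b had an Immature peak farther inside. Fcer2a (57.1), encoding CD23, was also called. In all, 293 genes were called, 197 protein-coding and 96 lncRNA, of which 177 had a peak overlapping none in Immature. They included 3 of 16 mature and follicular genes (Fisher's exact adjusted p = 0.0728) and 3 of 14 homing receptor genes (Fisher's exact adjusted p = 0.0689), neither past the threshold. Tbx21 (fold 38.2), Cebpa (31.7) and Il5ra (22.1), genes listed for natural killer, myeloid and B1 cells, were called as well, Il5ra with an Immature peak farther inside, and the full Mature list alone marked the granulocyte genes S100a8, S100a9, Lyz2 and Csf3r. With full lists myeloid markers (5 of 8, Fisher's exact adjusted p = 0.00893) and regulators of development outside blood (5 of 6, Fisher's exact adjusted p = 0.00165) passed. Immature over Mature held 11 genes, among them Il7r (fold 16.7), the interleukin-7 receptor gene, and Cfp (20.8), with 6 overlapping none in Mature. Full lists gave 1519 and 40 genes in the same directions, and the 40 included 4 of 17 pro-B and pre-B genes (Fisher's exact adjusted p = 6.56e-06).

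Mature marrow cells and Follicular spleen cells, both recirculating resting cells, differed in 1 direction. The Mature list held 356 called genes, 236 protein-coding and 120 lncRNA, and Follicular over Mature held 0, or 10 when both lists were limited to equal length. Cd93 (fold 19.8) was called for Mature, and its product AA4.1 was absent by gate from the Follicular sort. Gypa (25.2), an erythroid gene, and Il5ra (22.1, with a Follicular peak farther inside) were also called. Only 164 of the 356 had a peak overlapping none in Follicular, and the 6 strongest protein-coding genes, Lmbrd1, Gtf2ird2, Mrpl4, Btbd18, Supv3l1 and Ankrd12, were not among these. No gene list passed the threshold in either direction on the main calls. Full lists gave 1966 genes for Mature over Follicular, and myeloid markers (6 of 8, Fisher's exact adjusted p = 0.00236) and regulators of development outside blood (4 of 6, Fisher's exact adjusted p = 0.0368) passed.

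Follicular and Marginal cells, the resting B cells of the spleen, were parted by the gate on Cd23 and IgM. Marginal over Follicular held 27 genes, 24 protein-coding and 3 lncRNA, with Fcrl5 (fold 7.89), a marginal zone gene on chromosome 3 (87435777 to 87500678), Akr1e1 (11.8), Tmod1 (10.1) and the purinergic receptor gene P2ry1 (9.2) among the 21 whose peak overlapped none in Follicular. Follicular over Marginal held 219 genes, 166 protein-coding and 53 lncRNA, of which 150 overlapped none, but none of the 10 genes that the naming rule selected was among these. The strongest, such as the ferritin gene Fth1 and its neighbour Best1, which share a peak (fold 35.3), Ss18 (41.1) and Zmym4 (38.0), overlapped a Marginal peak. Fcer2a, which encodes the gated Cd23, was marked in both lists. No gene list passed, and full lists gave 157 genes for Marginal and 695 for Follicular.

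Germinal cells, sorted after immunisation as Cd38 low, PNA high, Fas and GL7 positive, had H3K4me3 at Aicda (fold 8.16, peak at 122553878 to 122555326 on chromosome 6), which encodes the deaminase that mutates antibody genes, at Mef2b (7.9), a transcription factor gene, at Rgs13 (9.85), a regulator of G-protein signalling, and at Gcsam (4.31), all without a peak at a gene end in Follicular, which had a peak farther inside Mef2b. These 4 of 17 germinal centre genes, 23.5% against 1.83% of the background, passed the test (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.034). Jchain (9.41), which encodes the joining chain of secreted IgM and IgA, Ankle1 (14.9) and the lncRNA Fendrr (6.12) were also called, among 265 genes (200 protein-coding and 65 lncRNA), of which 246 overlapped none in Follicular. The gated genes Fas and Cd38 were marked in all 8 lists. In the opposite direction 328 genes were called, 235 protein-coding and 93 lncRNA, with 269 overlapping none. They included the transcription factor genes Sox4 (fold 17.9) and Bhlhe41 (11.5, with a Germinal peak farther inside), with Plac8 (15.7) and Gfra1 (13.5), and no list passed. Full lists gave 422 genes for Germinal and 730 for Follicular, while equal-length lists turned the balance, with 607 for Germinal and 483 for Follicular. Immunisation and age differ along with the cell type in this pair.

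B1a cells, the innate-like B cells of the peritoneal cavity, had H3K4me3 at Cd5 (fold 25.3, gene on chromosome 19, 10718107 to 10739026), which their gate selects, and at Ctla4 (28.3), an inhibitory receptor gene, Il5ra (29.5), the interleukin-5 receptor gene, and Itgam (25.8), encoding CD11b, all without a peak at a gene end in Follicular, which had a peak farther inside Il5ra. These 4 of 13 B1 genes, 30.8% against 3.33% of the background, did not pass (Fisher's exact adjusted p = 0.056). Fcrl5 (44.8), the dendritic cell factor gene Batf3 (48.6), the chemokine receptor gene Ccr10 (25.1), the Hox gene Hoxd13 (24.7) and Krt222 (69.0) were also called. In all, 615 genes were called, 417 protein-coding and 198 lncRNA, of which 376 overlapped none in Follicular. Follicular over B1a held 2 genes, Fcer2a (fold 14.5), whose product Cd23 the B1a gate excludes, and the calcium channel gene Ryr2 (12.4), and both peaks overlapped none in B1a. In the full lists B1a marked 7 T-cell markers, 5 myeloid markers and 10 regulators of development outside blood, against 2 of each in Follicular, and with full lists T-cell markers (5 of 7, Fisher's exact adjusted p = 0.035) and the regulators (8 of 10, Fisher's exact adjusted p = 0.00119) passed for B1a. Full lists gave 3040 genes for B1a and 17 for Follicular.

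Distal H3K4me1, taken as peaks more than 1 kb from every annotated gene end and within a gene or 10 kb of it, also differed between neighbours, but which population of a pair had more such genes depended on list length. Pre over Pro held 1113 genes and Pro over Pre 806, Pre over Immature 897 and Immature over Pre 693, and Mature over Immature 904 against 288. The strongest Mature peaks of this kind included 1 at Setbp1 on chromosome 18 (79035183 to 79038213, fold 18.4) and 1 beside the class II gene H2-Ab1 on chromosome 17 (34255872 to 34257684, fold 11.7). Among the long lists few genes were called, 14 for Mature over Follicular, 51 for Follicular over Mature, 51 for Follicular over Marginal and 20 for Marginal over Follicular. S1pr1, a receptor for egress from lymphoid organs, was called for Follicular over Mature (115702591 to 115706112 on chromosome 3, fold 14.8). Follicular over Germinal held 393 genes, led by the class II gene H2-Eb1 (fold 17.5), and Germinal over Follicular 170, including Gcsam (7.38). Follicular over B1a held 228, including Rgs13 (fold 12.5), and B1a over Follicular 132. With both lists at equal length the balance turned in 5 of the 7 pairs. Pro over Pre then gave 1289 genes against 1113, Immature over Pre 1208 against 1017, Immature over Mature 1365 against 1011, Germinal over Follicular 1290 against 1065 and B1a over Follicular 1228 against 978. It did not turn for Follicular over Mature (844 against 758) or Follicular over Marginal (809 against 715).

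Taking Pro, Pre and Immature as precursors and Mature, Follicular, Marginal and B1a as resting mature cells, genes were sought with H3K4me3 in every list of a side and none of the other. Precursors shared 7 such genes. The 3 protein-coding ones were Rag1 and Rag2, whose products cleave DNA in V(D)J recombination, and Il7r. In Pro their peaks had folds of 34.7 (Rag1, chromosome 2, 101645992 to 101650560), 31.8 (Rag2, chromosome 2, 101624301 to 101626938) and 40.7 (Il7r, chromosome 15, 9526996 to 9530664). The other 4 were the lncRNA genes Gm32196, Gm34095, Gm40608 and Gm52705. None of the 7 was marked in Germinal. Rag2 is precursor-only at its ends alone, since Mature (101628112 to 101629260, fold 22.9), Follicular (fold 8.32) and B1a (fold 7.53) had H3K4me3 inside the gene. With peaks anywhere in the gene counted, 4 of the 7 stayed, Rag1, Il7r, Gm32196 and Gm52705. The pro-B and pre-B list passed (3 of 21 genes called against 0.0235% of the background, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.2e-06). Mature cells shared 42 genes, 32 protein-coding and 10 lncRNA, of which 13 were marked in Germinal. They included Cr2 (fold 51.6 in Mature), Gpr183 (57.3), Tnfrsf13b (30.0, with peaks farther inside in all 3 precursors), the immunity GTPase genes Gimap3 (60.5) and Gimap4 (63.2), and Ly6a (36.6), with the folds of the last 5 from the B1a list, and Slamf1 (39.7 in Mature). Of the mature and follicular genes 2 of 16 were called (Fisher's exact adjusted p = 0.056). Of the 35 splits of these 7 lists into 3 and 4, 6 gave at least 49 genes, so the total was not beyond chance. Leaving out Pre or Mature gave 16 or 17 precursor genes, and leaving out Pro, Immature or Marginal gave 88, 97 or 120 mature genes.

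**Figure D5:**
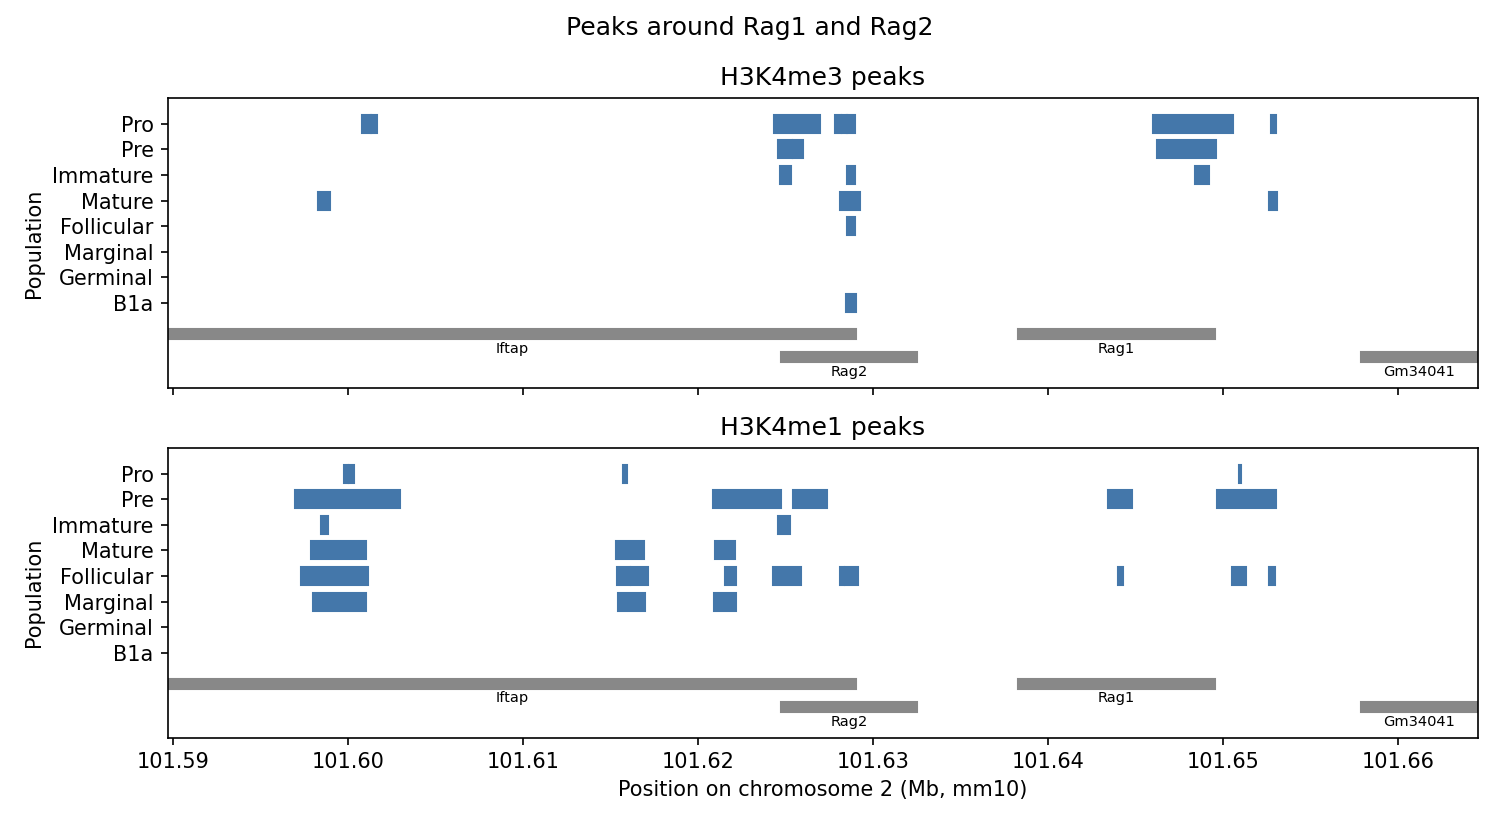
Peaks (blue blocks) of each population (vertical axis) around Rag2 and Rag1 on chromosome 2 (horizontal axis, Mb, mm10), H3K4me3 above and H3K4me1 below, with annotated genes in grey. H3K4me3 lies at an end of Rag1 and of Rag2 in Pro, Pre and Immature, and inside Rag2 in Mature, Follicular and B1a also, with Pro peaks at 101645992 to 101650560 and 101624301 to 101626938.

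Distal H3K4me1 separated the same groups of populations on equal-length lists, with 75 regions shared by precursors alone and 121 by mature cells alone. Within 10 kb of listed genes, mature regions lay at the B-lineage factor genes Ebf1 (chromosome 11, 44739502 to 44750439 and 44655278 to 44666330) and Ikzf3, the survival gene Bcl2 (chromosome 1, 106574445 to 106583093), the plasma cell factor gene Prdm1 and the lncRNA gene Pvt1 (chromosome 15, 62175165 to 62183098), and a precursor region at Itgam. The related survival gene Bcl2l1, in no list, had 3 precursor regions (chromosome 2, 152787729 to 152816325). A precursor region lay in Iftap, next to Rag2 (chromosome 2, 101596951 to 101602951), where the full lists of Mature, Follicular and Marginal also held H3K4me1. Of the 35 splits, only the real one gave as many regions, but these groups also differ in the strength at which the equal-length cut falls. Full lists, in which mature populations have many more peaks, gave 3 precursor and 3451 mature regions, and leave-one-out counts reached 241 and 285.

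Immunoglobulin kappa V segments carried H3K4me1 in some populations. Of 162 Igkv segments, 60 in Marginal, 44 in Follicular, 44 in Pre and 34 in Mature had a peak within 500 bp, against 15 in Immature, 7 in Germinal, 3 in B1a and 2 in Pro. H3K4me3 was found at 17 Igkv segments in B1a, 12 in Immature, 10 in Mature, 4 in Pre, 2 in Pro, 1 in Follicular and 0 in Marginal and Germinal. Of 183 Ighv segments, at most 5 had either mark in any population, and each of the 3 Iglv segments had H3K4me1 in Mature, Follicular and Marginal. V segments of the T-cell receptor loci, measured as a background, numbered 0 or 1 per locus, of 130 Trav, 35 Trbv, 7 Trgv and 6 Trdv segments. Trgv had H3K4me1 at 1 of 7 in each of Mature, Follicular and Marginal, so this small locus gives only a coarse background. Segments resemble each other, so these counts may depend on how reads with several matches were treated, which was not tested. On equal-length lists the sum over populations for Igkv H3K4me1 was 44 in place of 209.

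Core B-lineage genes carried unusually broad H3K4me3. In Mature, 21 of the 22 marked core genes were in the broadest 5% of marked protein-coding genes, with 19 of 22 in B1a, 18 of 22 in Follicular, 16 of 22 each in Immature and Marginal, and 9 of 20 each in Pro and Pre. Pax5, Ebf1 and Ikzf1, transcription factor genes of the lineage, were in that group in all 8 populations. The enrichment passed in 7 of 8 populations (Fisher's exact test, Benjamini-Hochberg adjusted p from 5.74e-26 in Mature to 2.17e-07 in Pro and Pre). In Germinal, 3 of 22 were in the broadest 5%, which did not pass (Fisher's exact adjusted p = 0.0952). Germinal did pass under both other settings, with 8 of 22 in the broadest 10% (Fisher's exact adjusted p = 0.000876) and 5 of 22 by the length of the widest peak (Fisher's exact adjusted p = 0.00409). Whether Germinal differed from the other populations was not tested.

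The share of the strongest H3K4me1 peaks that overlapped an H3K4me3 peak of the same population was 63.7% in Mature and 44.9% in B1a, against 23.3% in Marginal, 21.4% in Pre, 20.5% in Follicular, 20.2% in Immature, 18.0% in Pro and 9.13% in Germinal. The full H3K4me3 lists of Mature and B1a also covered the most sequence to overlap, 31.5 and 38.6 Mb against at most 22.7 Mb elsewhere. By the labels, only B1a had the same replicate numbers for both marks, and the Mature lists shared none. The overlap, like the shares with H3K4me1 alone, thus partly joins separate replicates. Bone marrow populations averaged 30.8% ± 22.0 and the others 24.5% ± 14.9 (SD, n = 4 each), a difference of 6.37 points within the spread (two-sided exact permutation p = 0.686). Without Mature the difference was -4.6 points, and on full lists -0.629.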

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

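Chosen only after the result was seen were both tests of the promoter differences over 6 pairs, which took the place of tests over 4 pairs written earlier, and, for H3K4me1 near gene ends, the tests of longer lists and of length and width together, and that last pattern was itself defined after its values were seen.

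B1a held 7545 H3K4me3 regions found in no other population, against 1451 in Mature, the next highest, a gap of 0.808 of the whole range. Of 23 groups of 8 lists examined by Dixon's ratio it was the only one beyond the critical value. Chance alone gives about 1 in 20, so a count of 1 among 23 is about what chance gives. That count ignores how far the gap of 0.808 lies past the critical value. The 23 groups also come from the same populations and are not independent. The count therefore cannot decide whether chance explains the B1a value. B1a also had the longest H3K4me3 list, with 31242 peaks. On chromosome Y, which female mice lack, the lists held 62 peaks, all between 90739734 and 90809682, and none at 4 Y-linked marker genes. A single cluster without marker genes does not show male cells, and its source was not tested.

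In 6 of 7 pairs of populations at least 80% of the called promoters lay in 1 direction, toward Pro and Immature over Pre, Mature over Immature, Mature and B1a over Follicular, and Follicular over Marginal. List length as the whole cause was argued against, since with lists of equal length the same population still held 85.5% to 99.0% of the genes called in either direction, and in the Follicular and Marginal pair it was the shorter list (18691 against 19025 peaks). Loss of weak peaks from the list with fewer calls stays open, because the called genes had median ranks at 83.6% to 91.0% of the equal-length list, against 34.4% to 36.0% for all marked genes, but also at 88.2% in the Follicular and Germinal pair, which was balanced. Of the 722 genes marked in 7 of 8 lists, 474 lacked a peak in Pre, 144 in Germinal, 87 in Marginal, 15 in Follicular and 2 in Pro. Peak width also stays open as untested, since in all 6 pairs the list with more calls had the wider H3K4me3 peaks. Median widths in the full lists were 951 bp in Pro and 900 in Immature against 745 in Pre. They were 1030 in Mature, 992 in B1a, 741 in Follicular, 553 in Marginal and 715 in Germinal. A difference between the cells themselves stays open as untested, because each population has 1 list.

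The Mature list alone marked S100a8 (fold 6.57), S100a9 (8.57), Lyz2 (10.3) and Csf3r (8.4), genes of granulocytes and other myeloid cells, with ranks from 80.4% to 95.9% of the list, among its weaker peaks. The 4 genes were picked because no other list marked them, so the lists cannot test whether longer lists bring such marks. Other blood cells in the sort are a candidate source that the tables leave open, as 20% of the 20 further granulocyte genes were marked in Mature (Anxa1, Mmp9, Ptafr and Mcemp1), between the bounds set in advance of under 20% and at least 50%. B1a marked 15% of the same genes and the other lists at most 5%, and 3 of those 4 genes were also among the B1a marks, so they are not specific. A difference between the cells themselves stays open as untested.

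Between 33.9% and 39.7% of H3K4me1 peaks lay within 1 kb of a gene end in Pre, Mature, Follicular and Marginal, against 17.4% to 21.0% in the other 4 lists. Longer lists alone were argued against, because at equal length Pre lay 14.1 percentage points above the higher of Germinal and B1a. Wider peaks alone were argued against too, because counted by the middle of each peak the 4 lists averaged 9.25 points above the others. With both taken away the gap was 2.27 points, so length and width together may account for most of the pattern. A difference between the populations in where H3K4me1 lies stays open as untested.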

How the results depend on the processing

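The settings chosen after seeing the data were absence from the whole gene, peaks at no other gene end, peaks overlapping none of the other list, peaks anywhere in the gene, and leaving out populations for the lncRNA shares. No paired analysis was possible because each list joins its replicates and carries no replicate number. Single replicates could not be left out for the same reason, and the setting with the most upstream start site alone was not run, since the annotation has no strand. Of 285 alternatives over 53 results, 172 counted as unchanged. Tested results then kept their direction and side of the threshold, counts stayed within 1.5 times, and shares of regions within a 95% binomial interval. That interval takes regions as independent and measures no spread between lists. All alternatives of the 3 lncRNA shares and of breadth counted as unchanged. Germinal still also passed for breadth under both alternatives (8 populations in place of 7). The H3K4me1-alone difference rose to 40.2 points with full lists and 38.7 with a -log10 q of at least 5. The cause of the changes below was not tested unless stated.

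With Pro, Pre and Immature against the other 5 populations, the tests of H3K4me1 number (-24883) and similarity (0.0947) passed, both exact permutation p = 0.0357, and H3K4me3 similarity turned to -0.0234. Base pairs covered turned the H3K4me3 difference to 1630885 and the correlation of peak numbers to -0.0839. Full lists turned H3K4me3 similarity to -0.00281 and the overlap of the marks to -0.629. Leaving out each population gave -3253 to 1795 for H3K4me3 number, -0.0104 to 0.0641 for H3K4me1 similarity, -0.0202 to 0.0647 for H3K4me3 similarity and -4.6 to 13.2 for overlap.

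Merging within 500 bp gave 25.4% of H3K4me1 regions in 1 population and 1.83% in all 8, and 29.5% and 36.5% for H3K4me3. Equal-length lists gave 56.7%, 0.972%, 12.0% and 61.7%. A -log10 q of at least 5 gave 0.0141% of H3K4me1 regions in all 8, since it leaves Pro 14 peaks, and 31.6% of H3K4me3 regions in 1 population.

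For promoters, full lists gave 2284 (Pro over Pre), 1648 (Immature over Pre), 40 (Immature over Mature), 1519 (Mature over Immature), 1966 (Mature over Follicular), 695 (Follicular over Marginal), 157 (Marginal over Follicular), 730 (Follicular over Germinal), 422 (Germinal over Follicular), 17 (Follicular over B1a) and 3040 (B1a over Follicular). More weak peaks enter by construction. Equal-length lists gave 98 (Pre over Pro), 92 (Pre over Immature), 129 (Immature over Mature), 761 (Mature over Immature), 1008 (Mature over Follicular), 10 (Follicular over Mature), 706 (Follicular over Marginal), 111 (Marginal over Follicular), 607 (Germinal over Follicular, against 483 for the reverse), 170 (Follicular over B1a) and 1131 (B1a over Follicular). Absence from the whole gene gave 7 (Immature over Mature), 232 (Mature over Follicular) and 138 (Follicular over Marginal). Peaks at no other gene end gave 660 (Pro over Pre), 471 (Immature over Pre), 162 (Mature over Immature), 191 (Mature over Follicular), 142 (Follicular over Marginal), 208 (Follicular over Germinal), 174 (Germinal over Follicular) and 370 (B1a over Follicular). Peaks overlapping none of the other list gave 5 (Pre over Pro), 6 (Immature over Mature), 177 (Mature over Immature), 164 (Mature over Follicular) and 376 (B1a over Follicular). With full lists 16 list tests passed in place of 2.

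For distal H3K4me1, equal-length lists turned the balance of 5 pairs and gave 1289 (Pro over Pre, against 1113), 1208 (Immature over Pre, against 1017), 1365 (Immature over Mature, against 1011), 758 (Mature over Follicular), 844 (Follicular over Mature), 809 (Follicular over Marginal), 715 (Marginal over Follicular), 1065 (Follicular over Germinal), 1290 (Germinal over Follicular), 978 (Follicular over B1a) and 1228 (B1a over Follicular). A 50 kb window gave 1388 (Pro over Pre), 2007 (Pre over Pro), 1589 (Pre over Immature), 1125 (Immature over Pre), 1735 (Mature over Immature), 5 (Mature over Follicular), 31 (Follicular over Mature), 26 (Follicular over Marginal), 6 (Marginal over Follicular) and 689 (Follicular over Germinal).

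For precursor promoters, equal-length lists gave 27, peaks anywhere in the gene 4, and leaving out a population 7 to 17. Leaving out a population gave 42 to 120 mature promoters. Distal regions on full lists numbered 3 and 3451, and leaving out a population gave 80 to 241 and 151 to 285. For V segments, equal-length lists gave 0 and 0 (Ighv H3K4me1 and H3K4me3), 44 and 10 (Igkv) and 9 and 3 (Iglv), and the segment alone gave 7 for Ighv H3K4me1. Peak lists without read totals set a limit on all of these, since a missing peak cannot be told from a shallow library.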

Other observations

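The test of population specificity and the full-list gene list tests were written before their results were seen. Limiting the specificity test to lists with genes marked there alone was chosen only after its result was seen, and so was the count of lists able to reach 5 points.

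In the full B1a list, 10 of 20 regulators of development outside blood carried H3K4me3 at a gene end, among them Pax6, Sox1, Nkx2-5, Olig2 and Hoxc10, which no other list marked, and Hoxd9 and Hoxd13, which Mature marked too. With full lists set against each other, 8 of 10 such genes were called for B1a over Follicular (Fisher's exact adjusted p = 0.00119), 4 of 6 for Mature over Follicular (Fisher's exact adjusted p = 0.0368) and 5 of 6 for Mature over Immature (Fisher's exact adjusted p = 0.00165). Of 7 T-cell markers in the background, 5 were called for B1a over Follicular (Fisher's exact adjusted p = 0.035). Cd3g and Gata3 were marked in B1a alone and Il2ra in Pre and B1a, while Cd3e, Lck, Zap70 and Itk were marked in no list. T-cell markers also passed for Pro over Pre (4 of 5, Fisher's exact adjusted p = 0.0396), and through Il2ra alone for Pre over Pro and Pre over Immature. Myeloid markers passed for Mature over Follicular (6 of 8, Fisher's exact adjusted p = 0.00236), Mature over Immature (5 of 8, Fisher's exact adjusted p = 0.00893), Pro over Pre (4 of 4, Fisher's exact adjusted p = 0.0198) and Immature over Pre (3 of 3, Fisher's exact adjusted p = 0.035), so they were not particular to Mature. None of these passed on the main calls. Among B-cell lists, full lists also passed pro-B and pre-B genes for Immature over Mature (4 of 17, Fisher's exact adjusted p = 6.56e-06), Toll-like receptors for Immature over Pre (6 of 11, Fisher's exact adjusted p = 0.0198) and mature and follicular genes for mature over precursor populations (2 of 16, Fisher's exact adjusted p = 0.0249). For Pre over Pro, Pre over Immature and mature over precursor populations the calls were the same in both settings, and only the adjustment over all tests differed.

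Several listed genes were marked in few populations. Aicda was marked in Germinal and B1a, Jchain, Rgs13 and Gcsam in Germinal alone, and Mef2b in Pro, Mature, Germinal and B1a. Spn, Cd5, Ctla4 and Itgam were marked in B1a alone, and Dntt, Vpreb2, Igll1 and Enpep in Pro alone. Ccr9, a receptor for homing to the gut, was marked in B1a alone (fold 4.69), and Ccr6 in Mature and Follicular. A further list of 20 macrophage genes with H3K4me3, written after the main values were seen, gave 4 in Pro, 2 in Pre, 3 in Immature, 3 in Mature, 2 in Follicular, 2 in Marginal, 3 in Germinal and 7 in B1a.

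For the promoters that differ between precursor and resting mature populations, 6 of the 35 splits of the 7 lists gave as many genes as the real split (49), so chance was not excluded. The highest of the others gave 390, with Pro, Mature and B1a, the longest lists, on a side, which points to a structure of the lists. For distal H3K4me1, 1 of the 35 splits, the real one, gave as many regions (196, with 170 for the highest of the others, Mature, Follicular and Marginal against the rest). The equal-length cut falls at a different strength in each list. Every mature region had a strongest -log10 p of at least 53.3 and every precursor region at most 44.2. The split therefore also follows peak strength, and the count of splits cannot tell stage from it.

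A hypothesis tested was that far lncRNA genes with H3K4me3 are more often marked in a single population than protein-coding genes whose peaks have the same rank. The rank-matched difference averaged 1.72 percentage points over 8 populations and was above 0 in 5 of 8 (two-sided exact sign-flip permutation p = 0.0625), under the 5 points set in advance. The test could not decide, because a difference of 5 points was out of reach in 5 of 8 lists, in which under 5% of the marked far lncRNA genes were marked there alone. Pre and Follicular had no such gene of either class and Immature no far lncRNA gene. The 6 lists with such genes in either class averaged 2.29 points (5 above 0, exact sign-flip permutation p = 0.0625), and the 5 with both averaged 2.78 (5 above 0, exact sign-flip permutation p = 0.0625, the smallest possible). The hypothesis was left open. Without matching, 28.9% of marked far lncRNA genes in B1a were marked there alone, against 5.09% of protein-coding genes, and the matched protein-coding value was 23.5%.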
